A study of Rattus norvegicus and synthetic construct with 4 samples.

How the data were processed

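The series measured reporter activity of human islet CAGE elements in a rat insulinoma line derived from INS1 by STARR-seq. Per the labels' protocols, elements of 198 bp were synthesized within oligonucleotides of 230 bp, with an anchor of 16 bp on each side, cloned into a STARR-seq plasmid and given random barcodes of 16 bases. For each of 3 replicates 10 ug of the plasmid library was electroporated into the cells, which were harvested after 24 h. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, treated with DNase I, reverse transcribed with a primer specific to the reporter transcript, and treated with DpnI against remaining plasmid. Libraries were amplified in a pair of PCR rounds that were stopped in mid-log phase and sequenced on an Illumina HiSeq.

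The authors deposited raw counts per barcode, with 1 column for the plasmid DNA and 1 for each RNA replicate, and a table that pairs barcodes with elements. The counts are whole numbers and were not normalized, as judged from their values. The pairing table lists 86107 barcodes on 4323 elements, 60.1% of those designed, and each barcode has 1 element. Of these, 35153 barcodes (40.8%) and 3378 elements are in the count table. The deposited count table is described as filtered, and the filter is not given in the sources used here. In its values, every barcode has at least 10 plasmid DNA counts and a count in at least 1 RNA library, and every element has at least 2 barcodes. The 945 elements that were paired but not counted had a median of 2 barcodes. Read trimming, barcode matching and any use of molecular identifiers are not given in the sources used here. The genome build is hg19, per the submitters' processing notes. Element names hold the chromosome, a start counted from 0 and an end, and starts are printed counted from 1.

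Groups were taken from the sample titles, with 1 plasmid DNA library and 3 RNA libraries. Counts were summed over the barcodes of each element and tested with edgeR 4.0.16 (R 4.3.3) as RNA against plasmid DNA, with TMM normalization, a quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. The filter of at least 2 barcodes and 10 plasmid DNA counts removed 0 elements. The TMM factors were 1.47 for the DNA and 0.876, 0.895 and 0.870 for the RNA libraries. Activities are therefore relative to the centre of the library and not to a control sequence, and an activity below the centre is not repression. There is 1 DNA library, so the spread is that between RNA libraries alone (common dispersion 0.399) and SDs of ratios leave out the error of the DNA. The p-values measure the spread between separate electroporations of the same plasmid library.

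Ratios per library were normalized RNA over normalized DNA counts. The SE of a log2 ratio was derived as its absolute value over the square root of edgeR's F statistic. Correlations between libraries and the spread between barcodes used log2 ratios with a pseudocount of 0.5 counts. Differences and correlations over elements were tested by two-sided permutation tests with 100000 draws unless another number is given, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlapping pairs share at least 50 bp and use each element once. Clustered elements have another element of the pairing table within 1000 bp, and a region is a chain of elements whose starts follow each other within that distance. Within an overlapping pair, log2 ratios of the barcodes were compared by permutation, with exact enumeration where the number of splits allowed it, and adjusted over the 200 pairs. Intervals for the share of detected barcodes are exact (Clopper-Pearson). Plots were drawn with matplotlib 3.10.9.

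The element test was checked on counts simulated for the 3378 elements, with 50 elements at each changed fold. The test called 0 of the 3178 unchanged elements. The simulated RNA counts used the dispersion fitted to these data, and the simulated DNA counts varied by read sampling alone. This check therefore cannot show false calls from further error of the 1 DNA library or from RNA counts distributed in another way. The permutation tests gave p under 0.05 in 6.5% of 200 null differences and 5% of 200 null correlations.

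Elements were named by a rule set before the data were examined. It takes the 12 highest and the 12 lowest log2 ratios among elements past the threshold with at least 5 barcodes and the same direction in 3 of 3 RNA libraries, which 261 elements met. The main tests and most alternatives were also set then. The alternatives cover the normalization, the test (DESeq2 1.42.0, limma 3.58.1 with voom, limma with barcodes as the unit), the filters, the weight of barcodes, the pseudocount, the distances and leaving out each RNA replicate. Comparisons of element classes, pairs and chromosomes beyond those of overlapping pairs and of clustered against isolated elements were chosen after the data were examined.

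A human genome or annotation was not used here, and element names give no strand. Comparisons of promoter-proximal with distal elements, of orientations, of base composition and motifs within elements, and of gene lists had been planned and were therefore not run. No element is assigned to a gene.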

Results

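The data comprised barcode counts from a STARR-seq experiment on human pancreatic islet elements. STARR-seq is a reporter assay in which each plasmid carries a candidate regulatory sequence that drives its own transcription, so that the RNA made from a sequence, relative to its plasmid DNA, measures its activity. The library was designed with 7188 elements of 198 bp that had been defined by CAGE, a method that maps the 5' ends of transcripts, in human islets. Each plasmid also carried a random barcode of 16 bases, and every barcode marks a separately made plasmid of its element. The plasmids were electroporated into a rat insulinoma line derived from INS1, which serves as a model of the insulin-secreting beta cell, and RNA was taken after 24 h. There were 3 RNA libraries, from replicates that the labels call biological, and 1 library of the input plasmid DNA. The comparison implied by this design is RNA output against plasmid input for each element.

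The plasmid DNA library held 1079728 counts, and the RNA libraries held 211117, 197554 and 218571 counts. These counts covered 35153 barcodes on 3378 elements, 47.0% of those designed. The median element had 6 barcodes, and the number ranged from 2 to 133. The median barcode had 26 counts in the plasmid DNA and 1 count in each RNA library. RNA replicate 1 detected 62.0% of the barcodes (exact 95% confidence interval 61.5 to 62.5%), replicate 2 detected 65.1% (64.6 to 65.6%) and replicate 3 detected 67.6% (67.1 to 68.0%). Barcodes were taken as independent draws for these intervals, which therefore cover the sampling of barcodes only. The PCR reads carry no stated molecular identifier. Every barcode in the table had at least 10 plasmid DNA counts and at least 1 count in an RNA library, so plasmids without any RNA were not analysed here. Before normalization, leaving out such plasmids can only raise the RNA/DNA of an element. The centre was set on the same filtered barcodes, so whether low activities relative to it are upper limits is not known.

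RNA counts per barcode fell into separate low and high ranges in each RNA library. A count of 4 was found for 1775, 2040 and 2184 barcodes in the 3 libraries, against 12, 6 and 17 barcodes at a count of 5. The counts above this gap peaked at 16, 13 and 14. Barcodes with 5 or more counts made up 22.7, 22.1 and 23.4% of barcodes and held 87.8, 85.3 and 86.2% of the RNA counts.

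**Figure D1:**
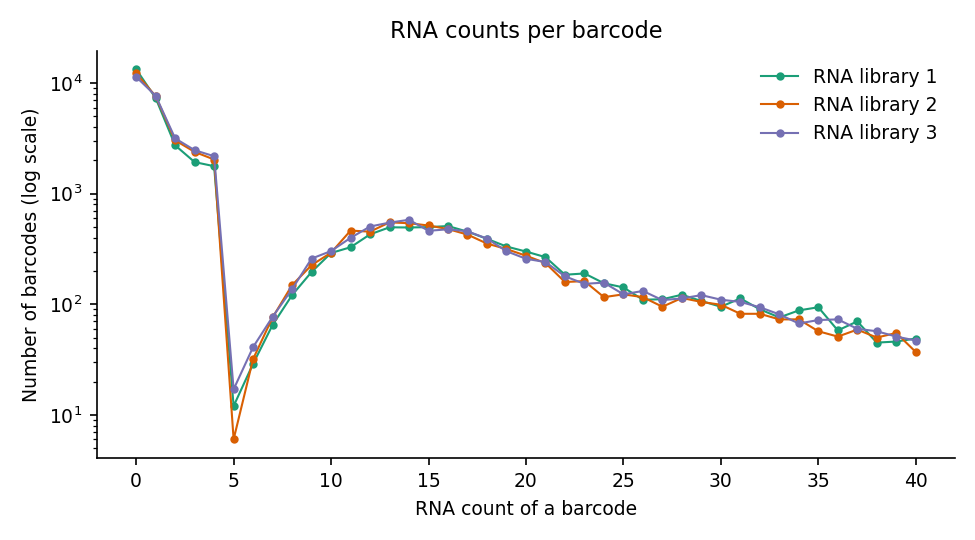
Number of barcodes (log axis) at each RNA count from 0 to 40, with 1 line for each of the 3 RNA libraries. In each library the number drops from at least 1775 barcodes at a count of 4 to at most 17 at a count of 5, and then rises to a second peak between 13 and 16.

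A minority of the islet elements gave RNA well above the centre of the library in the beta cell line. Of 3378 elements, 300 (8.88%) were above it in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. All 300 were higher in 3 of 3 RNA libraries. Their median was 5.42-fold (log2 2.44), with a range from 1.96-fold (log2 0.97) to 24.9-fold (log2 4.64). At least 4-fold activity was found for 204 of them, at least 8-fold for 65 and at least 16-fold for 10. Together the 300 elements held 46.8% ± 0.903 (SD, n = 3) of the RNA counts and 15.6% of the plasmid DNA counts. Across all elements, the 10th and 90th percentiles of RNA/DNA were 0.329 and 3.61 times the centre.

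The most active of the elements with at least 5 barcodes lay on chromosome 11 from 8704223 to 8704420 (hg19, as are all coordinates here). Its RNA/DNA was 23.2 ± 0.867 times the centre (SD, n = 3 RNA libraries over the 1 DNA library), from 27 barcodes with 926 DNA counts and 2613, 2331 and 2538 RNA counts. Its log2 ratio was 4.53 ± 0.22 (SE), with an adjusted p of 4.0e-30 in edgeR's quasi-likelihood test. An element on chromosome 22 from 38245338 to 38245535 followed at 20.6 ± 1.17 times the centre, and one on chromosome 19 from 8386311 to 8386508 at 19.3 ± 1.35 times. These rested on 7 and 6 barcodes. Chromosome 11 held 3 of the 12 highest elements. The other 2 spanned 63753816 to 63754013, at 18.1 ± 4.06 times the centre, and 65479624 to 65479821, at 14.3 ± 0.807 times. Chromosome 17 held 2, from 74553774 to 74553971 at 15.8 ± 2.61 times and from 41150364 to 41150561 at 14.1 ± 2.04 times.

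Among the 12 highest, 3 elements were carried by more than 20 barcodes besides the first. The element on chromosome 2 from 217363473 to 217363670 reached 16.3 ± 0.837 times the centre over 42 barcodes. An element on chromosome 1 from 201924541 to 201924738 reached 14.2 ± 1.23 times over 51 barcodes, and one on chromosome 5 from 54603734 to 54603931 reached 13.0 ± 0.558 times over 21. The remaining members were on chromosome 12 from 4758189 to 4758386, at 16.5 ± 2.43 times, and on chromosome 1 from 28157215 to 28157412, at 13.2 ± 1.33 times. All SDs are over 3 RNA libraries. The highest adjusted p among the 12 was 3.55e-08 in edgeR's quasi-likelihood test.

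**Figure D2:**
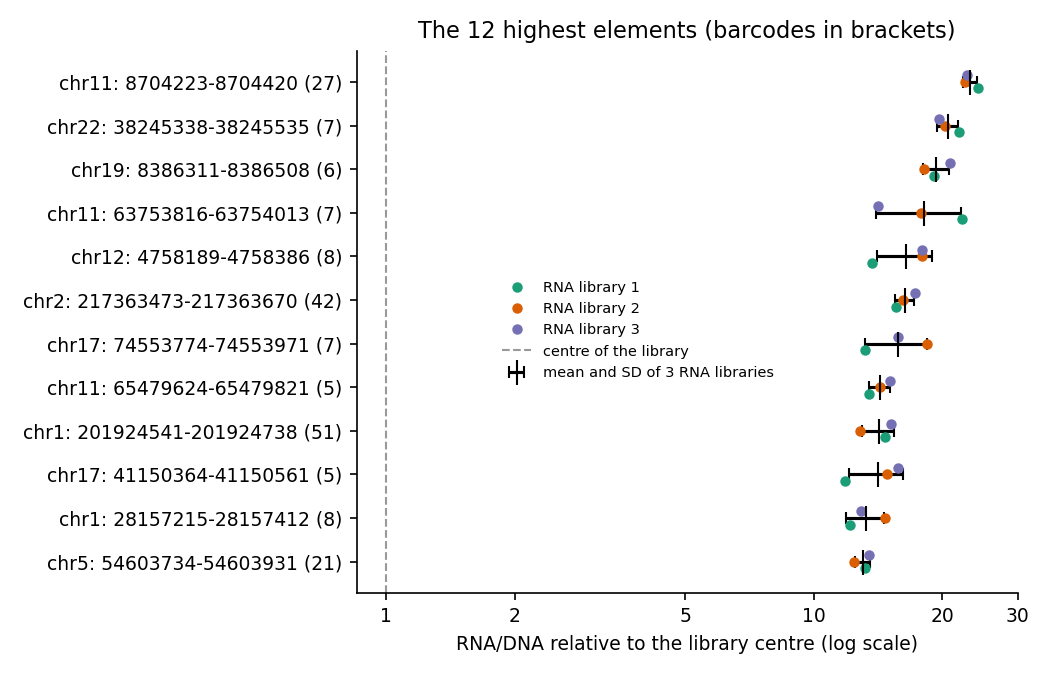
RNA/DNA relative to the library centre (log axis) of the 12 highest elements with at least 5 barcodes, named by chromosome and coordinates with the number of barcodes in brackets. Points are the 3 RNA libraries, ticks and bars are their mean and SD, and the dashed line marks the centre at 1. The means run from 13.0 to 23.2.

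The 12 weakest of the called elements with at least 5 barcodes lay between 1.96-fold and 2.52-fold above the centre and had 24 to 96 barcodes. An element on chromosome 1 from 115300513 to 115300710 had the lowest ratio of them, at 1.96 ± 0.0874 times the centre. The element with the most barcodes, 96, was on chromosome 2 from 175260305 to 175260502 and reached 2.36 ± 0.322 times the centre. Elements on chromosome 12 from 16035286 to 16035483 and on chromosome 20 from 33735025 to 33735222 were at 2.37 ± 0.394 and 2.35 ± 0.243 times (SD, n = 3 for each). A barcode is in the table only if it had an RNA count, so the number of barcodes depends in part on activity, and the share of elements called is given by that number as a description only. It was 3.38% of 1155 elements with 2 to 4 barcodes, 7.22% of 1080 with 5 to 9, 12.5% of 720 with 10 to 19, and 22.0% of 423 with 20 or more. The lowest called log2 ratio in these classes was 2.25, 1.87, 1.41 and 0.97.

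No element fell below the centre at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 26 elements were below and 457 above. DESeq2 called 0 below but left 1572 of the 3378 elements without an adjusted p. Below the centre, limma-voom called 136 and limma with barcodes as the unit 93. In counts simulated for these 3378 elements, the edgeR test recovered 82% of elements raised 8-fold and 32% of those raised 4-fold. It recovered 0% of those raised 2-fold or lowered to 0.25-fold. Each fold was given to 50 elements drawn at random, so these shares are averages over elements with few and many barcodes. In the data, rises of 1.96-fold to 2.52-fold were called in elements with 24 to 96 barcodes. Fewer elements were called in the simulation, 41 at 8-fold and 16 at 4-fold against 300 in the data. Its Benjamini-Hochberg cutoff was therefore stricter. The simulation therefore does not show which decreases are detectable in elements with many barcodes.

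The number of calls depends on where the centre is placed, on the low counts and on the test. With library totals in place of the TMM normalization, 169 elements were above and 50 below, the median log2 ratio moved by -0.73, and the 169 were among the 300. With RNA counts of 1 to 4 per barcode set to 0, 115 of the 300 were called, and without RNA replicate 2, 193 were. The number above was larger with limma-voom (511), with barcodes as the unit (490) and with the median over barcodes (470).

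Agreement between the RNA libraries was moderate over all elements and high for elements with many barcodes. Across 3378 elements, Pearson's r of log2 RNA/DNA was 0.522, 0.530 and 0.525 for the 3 pairs of libraries, with a mean of 0.526 ± 0.0044 (SD), and the mean Spearman's rho was 0.520. Elements are not independent replicates, so no p is given for these values. The mean r rose from 0.382 for elements with 2 barcodes to 0.423 with 3 or 4, 0.550 with 5 to 9, 0.661 with 10 to 19, 0.835 with 20 to 49 and 0.937 with 50 to 133. The median SD of log2 RNA/DNA between the 3 libraries fell over the same classes from 1.47 to 0.232. Because the 3 ratios share 1 DNA library, some correlation arises without any activity. Simulated unchanged elements gave r 0.0425 and a covariance of 0.0629 (mean of 100 draws), against an observed covariance of 1.52. The simulated DNA counts varied by read sampling alone (Poisson). Any further error of the 1 DNA library, which cannot be estimated here, would add shared correlation that this simulation leaves out. The simulation also left out the filter that keeps a barcode only with a count in at least 1 RNA library. That filter can lower r, and 13180 of the 35153 barcodes were detected in only 1 RNA library.

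**Figure D3:**
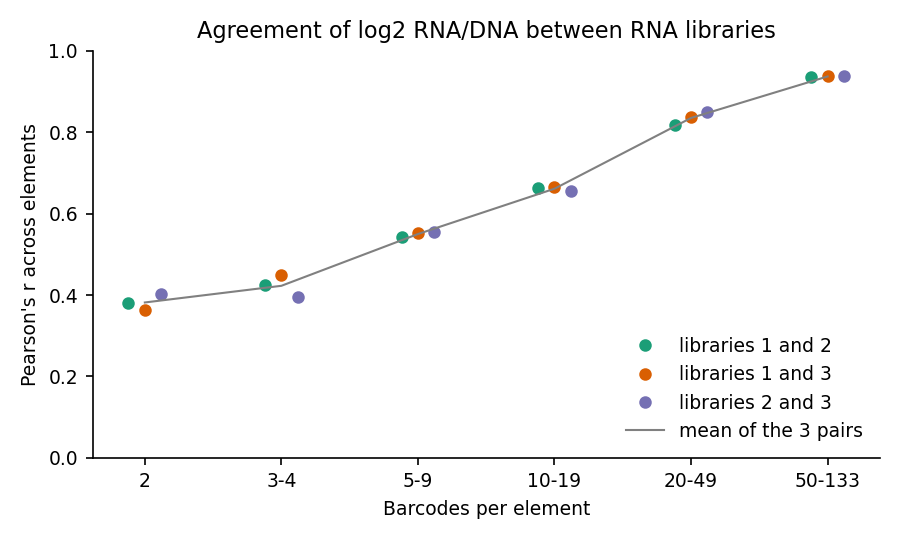
Pearson's r across elements of log2 RNA/DNA between RNA libraries, by the number of barcodes per element. Points are the 3 pairs of libraries and the line is their mean, which rises from 0.382 at 2 barcodes to 0.937 at 50 to 133.

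Separate plasmids carrying the same element gave variable ratios. Between barcodes of 1 element, log2 RNA/DNA had an SD of 1.76 ± 0.0394 (mean and SD over 3 RNA libraries) with a pseudocount of 0.5 and of 0.880 with a pseudocount of 5. This spread includes the counting noise of single barcodes, whose median was 1 RNA count, and was not separated from it. The barcodes of each element were divided at random into 2 parts, of equal size or, where their number was odd, differing by 1 barcode. The activities of the 2 parts, each taken from a different RNA library, correlated with r 0.366 over all elements. Over the 423 elements with at least 20 barcodes r was 0.698 (mean of 20 divisions for both). These parts share no plasmid and no DNA count, and the values also include the spread between libraries.

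Overlapping elements were compared to ask how far activity follows shared sequence. In 8 pairs, neighbours offset by 70 to 144 bp differed clearly in activity, and the highest of the elements with at least 5 barcodes was in 1 of them. The element on chromosome 11 from 8704223 to 8704420 was at 23.2 ± 0.867 times the centre, while its neighbour from 8704102 to 8704299, which shares 77 bp with it, was at 1.90 ± 1.12 times (SD, n = 3). The barcodes of the pair differed in a permutation test over barcodes, 27 against 6, with p = 1e-05, the smallest that 100000 permutations can give, and 0.00133 after Benjamini-Hochberg adjustment over the pairs tested. Of 200 pairs that share at least 50 bp, with each element used once, 8 differed in this way after adjustment and 36 before it. Pairs with few barcodes could not pass whatever their values, since the smallest p of this permutation test is 0.333 at 2 against 2 barcodes. How many pairs could pass was not counted, so the remaining pairs are not shown to be alike. In 7 of the 8 pairs 1 element was called above the centre and its neighbour was not. The higher member had the lower coordinate in 4 pairs and the higher coordinate in 4.

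On chromosome 1 the element from 28832407 to 28832604 was at 5.69 ± 1.05 times the centre and the one from 28832477 to 28832674, sharing 128 bp, at 0.651 ± 0.530 times. On chromosome 21 the values were 0.867 ± 0.630 from 27107120 to 27107317 and 4.59 ± 0.651 from 27107232 to 27107429. On chromosome 14 they were 1.24 ± 0.279 from 78174257 to 78174454 and 6.80 ± 0.818 from 78174344 to 78174541. On chromosome 2 they were 4.47 ± 0.850 from 113341949 to 113342146 and 1.41 ± 0.422 from 113342093 to 113342290. The pair on chromosome 12 starting at 16035286 and 16035386 had ratios of 2.37 ± 0.394 and 0.356 ± 0.285, and the pair on chromosome 20 starting at 34638855 and 34638955 had 3.22 ± 1.65 and 0.658 ± 0.105. On chromosome 6, neither member of the pair starting at 26124104 and 26124204 was called, at 0.415 ± 0.133 and 1.49 ± 0.388 (SD, n = 3 throughout). These pairs were named after their values were seen.

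**Figure D4:**
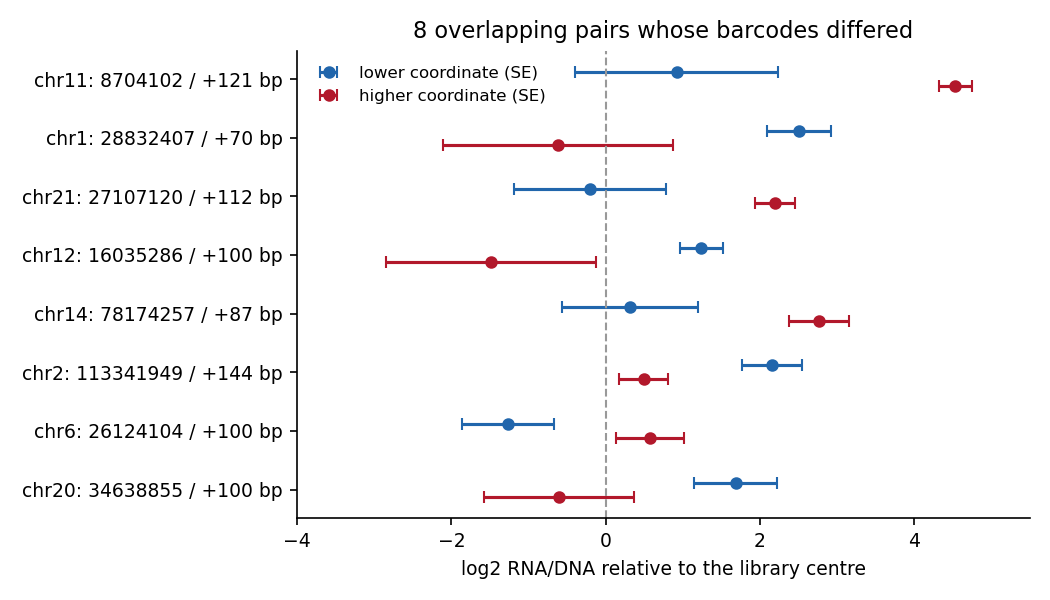
Log2 RNA/DNA relative to the library centre, with an SE derived from edgeR's F statistic, for the 8 overlapping pairs whose barcodes differed. Each pair is named by the start of its lower element and the offset of the other. Blue points are the element with the lower coordinate and red points the one with the higher coordinate, and in 4 pairs the blue point is higher.

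Over the 200 overlapping pairs, log2 RNA/DNA of the members was weakly correlated (Pearson's r 0.282, permutation p = 2e-05; Spearman's rho 0.249, permutation p = 0.00041). The same elements correlated with r 0.407 between single RNA libraries, so noise limits how high a correlation of pairs can be. The value of 0.282 rests on the 3 RNA libraries together and is not on the same footing as 0.407. The correlation of pairs in single libraries, given below, is the closer match. Of these pairs, 164 shared 98 bp at an offset of 100 bp. Both members were above the centre in 4 pairs, where 0.495 would be expected from the calls alone, 1 member in 12 pairs and neither in 184. The 4 pairs started at 153418357 and 153418446 on chromosome 5, at 47600425 and 47600511 and at 64889527 and 64889672 on chromosome 11, and at 32687846 and 32687925 on chromosome 1, and were named after their values were seen. For 191 pairs within 1000 bp that did not overlap, r was 0.0380 (permutation p = 0.604), and the difference of 0.244 between the correlations had p = 0.0123 by permutation of the kind of pair (20000 draws). The correlation in single RNA libraries was 0.195 ± 0.102 (SD, n = 3), and without RNA replicate 3 it was 0.179 (permutation p = 0.0111). It was 0.123 (permutation p = 0.0837) with RNA counts of 1 to 4 set to 0, and 0.0870 (permutation p = 0.661) over the 28 pairs with at least 10 barcodes on each member, whose elements correlated with r 0.603 between RNA libraries.

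Elements that stood close to other barcoded elements in the genome were less active than isolated ones. The 976 elements with another element paired with a barcode within 1000 bp had a mean log2 RNA/DNA of -0.21. The 2402 isolated elements had 0.16. Designed elements that were not paired with a barcode did not count as neighbours. The difference was -0.37 (95% bootstrap interval -0.47 to -0.27; two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). In the single RNA libraries it was -0.38 ± 0.04 (SD, n = 3). Above the centre were 54 clustered elements (5.53%) and 246 isolated elements (10.2%), with p = 7.06e-06 in Fisher's exact test. These tests take elements as independent, which neighbours are not. With the mean of each region as the unit, chosen after seeing the data, 476 clustered regions differed from the 2402 isolated elements by -0.32 (95% bootstrap interval -0.43 to -0.21; permutation p = 1e-05).

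Elements that overlapped a neighbour were the lowest class. The 603 overlapping elements had a mean log2 RNA/DNA of -0.32 and 4.81% were called above, and the 373 with a neighbour nearby but no overlap had -0.02 and 6.70%. Overlapping elements were lower than isolated ones by permutation test (difference -0.48, p = 1e-05, adjusted over 3 class comparisons by Benjamini-Hochberg 3.0e-05) and lower than those with a nearby neighbour (difference -0.30, permutation p = 0.00026, adjusted 0.00039). Elements with only a nearby neighbour differed from isolated ones by -0.18 (permutation p = 0.021, adjusted 0.021). With region means as the unit the 3 differences were -0.41, -0.23 and -0.25, with Benjamini-Hochberg adjusted permutation p of 6.0e-05, 0.0309 and 0.00972. The median number of barcodes was 6 in each of the 3 classes.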

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

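The settings with RNA counts of 1 to 4 set to 0, with barcode GC scaling, with matched elements or region means, and without overlapping elements or the chromosome 6 window were chosen after seeing the data. Elements above the centre numbered 169 with library totals, 490 with barcodes as the unit, 511 with limma-voom, 470 with the median over barcodes and 115 with low counts at 0, against 300. Below it were 50, 93, 136, 24 and 7 under these same settings, against 0. Leaving out 1 RNA replicate gave 193 (without replicate 2) to 289 above and 0 to 3 below (3 without replicate 1). Fewer libraries and a larger centre shift follow from the construction of those settings, and otherwise the cause was not tested. The other settings gave 268 to 419 above and 0 below, where DESeq2 left 1572 elements without an adjusted p. DESeq2, limma-voom, DESeq2 size factors in edgeR and centring on the mode each called all 300, and barcodes as the unit called 298. The setting with no filter removed no element and tests nothing.

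All 12 highest elements kept their direction and their side of the threshold in the 204 values computed under alternatives, with a lowest log2 of 2.96. The mean r between libraries was 0.620 with at least 5 barcodes, 0.545 with at least 50 DNA counts, 0.551 and 0.642 with pseudocounts of 1 and 5, and 0.522 to 0.530 with 1 replicate left out, against 0.526. The barcode SD was 1.83 with at least 5 barcodes, and 1.46 and 0.880 with pseudocounts of 1 and 5, against 1.76. The correlation of overlapping elements was 0.401 with at least 5 barcodes and 0.327 with the median over barcodes, against 0.282. With 1 replicate left out it was 0.179 to 0.289. It lost its threshold with low counts at 0 (0.123, permutation p = 0.0837). The same held with at least 100 bp shared (0.510, permutation p = 0.133), where few pairs were left. At 150 bp too few pairs remained for a value. The clustered difference stayed negative and past the threshold under each alternative run, from -0.18 without overlapping elements (permutation p = 0.0204) to -0.60 with low counts at 0. No paired analysis was possible because the plasmid DNA is 1 library without a replicate number. The depth of 1 median RNA count per barcode limits elements with few barcodes most.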

Other observations

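The tests of chromosomes, runs of tiles, plain read sampling, both kinds of carry-over and barcode composition within elements were chosen after the results were seen. Activity was lower on 2 of 22 chromosomes, each tested against all others by permutation with Benjamini-Hochberg adjustment and with regions, not elements, as the unit, because neighbouring elements are not independent. Elements on chromosome 6 (261 elements in 193 regions, mean log2 -0.39, 3.83% above, adjusted p = 0.00022) and 13 (59 in 53, -0.52, 6.78%, 0.0133) were low. With elements as the unit 5 chromosomes passed, and chromosomes 19 (206 elements, mean log2 0.34, 12.1% above), 17 (168, 0.33, 13.1%) and 4 (165, -0.22, 4.85%) did not pass with regions (adjusted permutation p = 0.0862 for each).

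Many elements tile a region at steps of 100 bp, and 60 runs of exactly 3 tiles were measured in full. The middle tile was above the mean of its flanks in 37 of the 60 runs, by 0.23 on average with an SD of 1.22 (permutation p = 0.157), and the lower-coordinate flank differed from the other by 0.15 (permutation p = 0.396), so neither place in the run stood out at this depth. The elements with the highest ratios of all had few barcodes and fall outside the naming rule, such as chromosome 11 from 47600511 to 47600708 at 24.9 ± 8.31 times the centre (SD, n = 3) from 2 barcodes.

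Elements on chromosome 6 between 26 and 27 Mb, a part of the genome known for the largest cluster of histone genes, were low as a group, although no element was assigned to a gene. The 36 elements, from 26020618 to 26597298, had a mean log2 of -0.96 against 0.06 for all others, a difference of -1.03 (-0.95 ± 0.02 in single libraries, SD, n = 3; -2.42 with RNA counts of 1 to 4 set to 0, -0.76 with barcodes as the unit and -0.70 with the median over barcodes), and 1 was called above, from 26597101 to 26597298, at 11.6 ± 1.07 times the centre. The other 225 elements of chromosome 6 were themselves lower than those of other chromosomes (difference -0.40), and against them the window differed by -0.66. Over region means, 19 of them in the window, these differences were -0.38 (permutation p = 0.00038) and -0.85 (permutation p = 0.00379). The window was picked for its low values, and no p against the rest of chromosome 6 allows for that choice. The tables argue against chance among the 29 windows with enough elements (permutation p = 0.00015 over elements and 0.00075 over regions, 20000 draws), against barcode number or DNA depth (difference from matched elements -1.01) and against barcode composition (difference after scaling -1.04). Of the 36 elements, 24 overlapped a neighbour, and overlapping elements were the lowest class. The 11 isolated ones were also lower than other isolated elements (difference -1.43, permutation p = 0.0008, not adjusted for picking the window). For those 11, this argues against overlap as the source. Low activity of these sequences in this cell line stays open as a hypothesis, as do barcodes paired with the wrong one of several near-identical sequences, which was not tested.

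The gap between low and high RNA counts per barcode is not what sampling gives. For any mix of abundances, the ratio of neighbouring frequencies weighted by the count cannot fall, yet it dropped from at least 3.41 at a count of 3 to at most 0.0389 at 4. Carry-over between RNA libraries as the whole source is argued against by the 63.7% of 30257 barcodes with a count of 1 to 4 that reached 5 in no library, although barcodes high in another library had counts of 1 to 4 more often (63.2% ± 4.02 against 39.2% ± 2.29, SD, n = 3). Carry-over of plasmid DNA as the whole source is argued against by a log-log slope on DNA of 0.135 ± 0.00978 (SD, n = 3) among barcodes at 0 to 4 in a library and at 5 or more in another, which the RNA filter of the table keeps whatever their count; proportionality gives 1, somewhat less because counts stop at 4, and a first form over all barcodes at 0 to 4, which that filter affects, gave 0.0833. A step of counting or PCR before deposit may separate the ranges, which was not tested, and no biological explanation was tested.

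RNA/DNA fell with the number of G and C bases in the barcode, from 0.229 ± 0.0119 at 2 such bases to 0.163 ± 0.00711 at 10 (SD, n = 3), and was 0.195 at 12. The tables argue against a chance link of such barcodes with weak elements, because the slope per base was -0.0429 ± 0.00897 against the expectation from each element's own ratio and -0.0491 ± 0.0102 when pooled. A first form of this test, on log2 ratios of single barcodes, gave -0.00785 ± 0.00316 within elements and -0.0112 ± 0.00403 pooled and did not decide, and the summed form was chosen afterwards. The trend does not set the calls, since 298 of the 300 were shared after scaling. Whether it arises in PCR or in the RNA stays open, and no biological explanation was tested.

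RNA rose less than in proportion to plasmid DNA, from an RNA/DNA of 0.352 in the fifth of barcodes with the fewest DNA counts to 0.136 in the fifth with the most, and this fall is at least partly built in, because barcodes were divided by the denominator of the ratio and enter the table only with an RNA count.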
